A study of Caenorhabditis elegans with 2 samples.

How the data were processed

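Chromatin immunoprecipitation was measured in 2 biological replicates of whole young adult worms expressing MADF-3 tagged with EGFP. Per the labels, chromatin was sheared by sonication, the antibody was against GFP and positions refer to build ce11. The labels call the samples biological replicates with separate biosample records. The aligner, the peak caller, its control and their versions are not given in the sources used here. Control libraries and read-level tracks were not used here.

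The deposited files are peak lists scored by the irreproducible discovery rate (IDR), which asks whether peaks keep their rank between compared sets of peaks. The signal of each peak is the peak caller's own strength as deposited by the authors, with its scaling not given in the sources used here. The ranked lists hold a −log10 of the IDR, deposited by the authors and capped at 5. The score of the thresholded lists is a whole number up to 1000 made from the IDR by the authors, and the lowest score in the series-wide thresholded list was 830. Per the deposited descriptions, the series-wide ranked lists were made from the alignments of both replicates with 1 further input file and the thresholded lists with 2, and the replicate lists from each replicate's alignments in the same way. What these further files hold is not given in the sources used here. All 2741 peaks of the series-wide thresholded list were rows of the ranked list made from both replicates, and all 2631 peaks of the conservative list were rows of the ranked list made by comparing the true replicates. In the former, 0 of 113502 peaks of a compared set were in replicate 1's own ranked list. In the latter, 64450 of 111167 were. A place in the thresholded list is therefore not read here as agreement between the replicates. Of its 2741 peaks, 2117 met a peak of the conservative list. Peaks were mostly of 1 width, with 94.6% of the series-wide peaks 220 bp wide, so width carries little information. No list gives read counts, so depth is unknown and intervals cover counting of peaks or genes only.

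The main list was the series-wide thresholded list. Summits were placed with the deposited offset, and coordinates are 1-based. Genes came from Ensembl release 115 on the same assembly as ce11, whose 6 nuclear chromosome lengths hold every peak end. The 5' end is the annotated gene start on its strand. A promoter peak is a summit within 500 bp of it on either side. Per-replicate signals of a named peak are the highest signal of an overlapping peak in each replicate's own ranked list, given as mean ± SD. Correlations used the per-replicate signals paired in the true-replicate ranked list on a log2 scale, as a description with no p-value.

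Circular shifts moved all summits of a chromosome together by a random distance, 1000 times, and p-values are two-sided. Shares of X and of chromosome centres had exact binomial tests. The 31 gene lists were compared with all other protein-coding genes by Fisher's exact test, with Woolf intervals on the odds ratio and Benjamini-Hochberg adjustment over the lists. The lists were the madf family, ribosomal proteins, mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, proteasome, histones, splicing factors, vacuolar ATPase, respiratory chain, chaperones, autophagy, small RNA pathway, DREAM and synMuv B, cell cycle, germline and meiosis, oocyte and eggshell, vitellogenins, intestine, muscle, neurons, neuropeptides, cuticle collagens, nuclear hormone receptors, homeobox, bHLH, chemoreceptors, F-box, C-type lectins and detoxification, and 1 more whose result is not reported here. Non-coding classes with at least 20 genes were tested by the shifts, adjusted over 10 classes. GC was compared between the summit window and both flanks with 100000 sign flips. An 8-mer, taken with its reverse complement, needed 20 peaks and was compared between the summit window and 1 flank chosen by coin flip with an exact McNemar test, found on I, III and V and tested again on II, IV and X. The threshold was an adjusted p of 0.05.

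Groups, tests, lists, fixed sequences, alternative settings and the rule for named genes were set before the data were examined. The rule took madf-3 and madf genes with a promoter peak, the gene nearest to each of the 15 strongest summits if within 500 bp, the 2 members with the strongest promoter peak of each list that passed, and genes in a count of 5 or fewer. Alternatives were the conservative list, the 1370 stronger peaks, each replicate's own list, windows of 200 and 1000 bp, other backgrounds, autosomes alone, shifts in place of Fisher's test, other overlap rules and flanks 400 to 500 bp away. Tests of regions other than promoters were chosen after seeing the data, and other alternatives and tests so chosen are named in the closing parts.

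The scripts were tested on simulated data. Raising the share of genes with a peak in 6 gene lists, over 19973 genes, led to all 6 being found, and with no list raised 1 of 540 list tests passed. Each simulated gene got its peak independently, while 432 of the 1251 real genes with a promoter peak share one. That rate of 1 in 540 therefore does not cover neighbouring genes that share a peak. A planted 8-mer was recovered from 1500 simulated summits, and 0 passed when none was planted. The simulated summits were random positions without the higher GC of the real ones. That count of 0 therefore does not cover 8-mers that differ through base composition. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.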

Results

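Binding of MADF-3, a nematode protein named for its MADF domain (a DNA-binding domain related to Myb), was profiled by chromatin immunoprecipitation and sequencing in whole young adult Caenorhabditis elegans. The worms carried TY1, EGFP and 3xFLAG tags inserted by CRISPR at the madf-3 gene itself, and chromatin was pulled down with an antibody against GFP. Animals were synchronised as starved L1 larvae and collected as young adults at 63 hours. The 2 samples are biological replicates of 1 group, so the comparisons below are between the replicates, between places in the genome and between groups of genes. The files hold peaks and no read counts, so the depth of each library is unknown. The series-wide thresholded list held 2741 peaks, the replicate 1 list 962 and the replicate 2 list 863. Positions are given for build ce11.

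The strongest peaks of the thresholded list mostly lay just upstream of protein-coding genes, among them hsr-9, rps-19, epc-1, snr-4 and taf-4. The peak with the highest signal in the thresholded list, on chromosome I from 9625944 to 9626209, lay in the intergenic space between the divergent genes hsr-9 (WBGene00002027), an orthologue of the DNA damage protein 53BP1, and rps-19 (WBGene00004488), a protein of the small ribosomal subunit. Its summit was at -163 bp from the 5' end of hsr-9 and -282 bp from that of rps-19, where negative is upstream, and the signal in the replicates' own lists was 1704 ± 124.95 (SD, n = 2). The next peak, on III from 9765442 to 9765789, was intergenic with no protein-coding 5' end within 500 bp and had a signal of 1441 ± 114 (SD, n = 2). A peak on III from 12608595 to 12608966, at -236 bp from epc-1 (WBGene00007030), a homologue of Enhancer of Polycomb, had 1116 ± 14 (SD, n = 2). At snr-4 (WBGene00004917), which encodes an Sm protein of the spliceosome, the peak on V from 11979935 to 11980206 had 860 ± 1.05 (SD, n = 2). At taf-4 (WBGene00006385), a subunit of the general transcription factor TFIID, the peak on I from 382400 to 382632 had 572 ± 8.31 (SD, n = 2).

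Of the 15 peaks with the highest signal in the thresholded list, 14 had a protein-coding 5' end within 500 bp, and all 14 summits were upstream of it. The other genes so named were F09G2.2, Y39E4B.6, K04G7.1, tos-1, rbm-39, unc-40, tsr-2, W03C9.5, rsp-1 and vha-1. Among these, rbm-39 encodes an RNA-binding protein, rsp-1 an SR splicing protein, unc-40 the netrin receptor and vha-1 a subunit of the vacuolar proton pump. The summit was at -10 bp from rbm-39, where the signal was 640 ± 56.9 (SD, n = 2), and at -281 bp from unc-40, where it was 612 ± 39.6 (SD, n = 2). All 15 peaks were met by a peak in the thresholded list of each replicate. The signal is the authors' value for each peak, and peaks were ranked by it only within a list. Each mean ± SD joins 1 value from each replicate's own list. The scaling of these lists is not given, so the SD may also hold a difference in scale between the libraries. The ranked list held a stronger peak, with a signal of 3508 on X, that is not in the thresholded list, which was made with 1 further input file. Among ranked peaks with a score that reaches the lowest of the thresholded list, 4 of the 10 strongest and 18 of the 50 strongest are missing from it. Of the 215 missing, 8 were at promoters, so the placement given here holds for the thresholded list only.

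**Figure D1:**
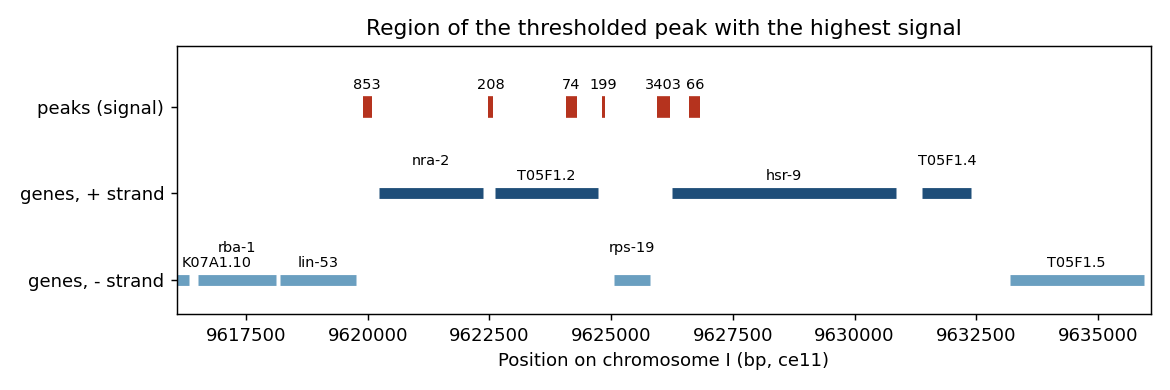
Protein-coding genes and thresholded peaks around the peak with the highest signal, drawn to scale along chromosome I in bp of build ce11, with genes by strand and the authors' signal above each peak. The peak with a signal of 3403 lies between rps-19 and hsr-9, and the peak with a signal of 853 lies upstream of lin-53.

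The replicates marked many of the same places. Of the 962 peaks of replicate 1, 576 (59.9%, exact 95% interval 56.7 to 63.0%) met a peak of replicate 2 by at least 1 bp, against a mean of 0.362% when the other list was shifted around each chromosome. The same 576 overlaps were 66.7% of the 863 peaks of replicate 2 (interval 63.5 to 69.9%). No shift of the 1000 came close, with at most 10 overlaps, and the permutation p of 0.0020 (two-sided) is the smallest they can give. Of the 250 series-wide peaks with the highest signal, 249 were met in each replicate's list, compared with 895 of 2741 (32.7%) for replicate 1 and 830 of 2741 (30.3%) for replicate 2 over the whole list. Across the 2631 peaks of the conservative list, log2 signal of the replicates had Spearman's rho of 0.468 and Pearson's r of 0.843, and 98.1% of peaks were within 2-fold. Those peaks were selected for being alike in rank between replicates, they are not independent, and over all 113670 ranked peaks rho was 0.359 and r 0.378.

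The peaks were sparse on the X chromosome. X held 325 of 2741 peaks (11.9%, exact 95% interval 10.7 to 13.1%) and 17.7% of the nuclear genome length, a ratio of 0.671 (exact binomial test, two-sided, p = 6.1e-17). Set against X's 13.7% of protein-coding genes the ratio was 0.867 (exact binomial p = 0.0054). At promoters, 62 of 2731 X genes (2.27%) had a peak, against 1189 of 17242 autosomal genes (6.90%). X's share of the peaks outside promoters was not tested on its own, so the shortage there may be smaller. Density ran from 18.3 peaks per Mb on X to 36.6 on III and 34.9 on I. Of the 250 strongest peaks, a set chosen after seeing the data, 6 lay on X (2.4%), a ratio of 0.136. That set leaves out the 215 ranked peaks missing from the thresholded list. Of these, 37 were on X, the strongest of all among them. On the autosomes, 1484 of 2416 peaks (61.4%) lay in the central 50% of the chromosome's length, a ratio of 1.23 (exact binomial p = 2.1e-29), and a ratio of 1.10 against the 55.7% of autosomal protein-coding genes found there (exact binomial p = 1.1e-08).

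Promoters held more of the peaks than shifted positions did. Of 2741 summits, 1082 (39.5%) were within 500 bp of a protein-coding 5' end, against a mean of 18.8% and a maximum of 21.3% over 1000 circular shifts (permutation p = 0.0020, two-sided, the smallest they can give). Tests of the other regions were chosen after seeing the data, and were made among the 1659 summits outside promoters because shares of all summits fall where the promoter share rises. Introns held 24.8% of these against 36.7% when shifted, intergenic space 41.2% against 35.4% and 3' UTRs 6.21% against 3.35% (adjusted permutation p = 0.0033 for each). Regions were drawn from protein-coding genes only, so intergenic space here includes RNA genes that lie outside them. Coding sequence held 26.8% against 24.0% (adjusted permutation p = 0.0080) and 5' UTRs 0.964% against 0.512% (adjusted permutation p = 0.0075). As shares of all 2741 summits, also tested after seeing the data, coding sequence held 16.2% against 19.5% and intergenic space 25% against 28.7% (adjusted permutation p = 0.0030 for each), and 5' UTRs did not pass (adjusted permutation p = 0.27). Summits at promoters had a median position of -109 bp from the nearest 5' end, and 740 of 1082 (68.4%) were upstream. These 1082 peaks gave 1251 of 19973 protein-coding genes a promoter peak (6.26%), and 214 of them lay at 2 or more genes. A 5' end in worms is often a trans-splice site rather than the start of transcription, which limits how finely these distances can be read. With a window of 200 bp 20.9% of summits were at promoters, against 7.82% when shifted, and 629 genes had a peak, and the lists of replicates 2 and 1 alone gave 570 and 604.

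The place of a peak went with its signal. Among the 100 strongest peaks 76.0% were at promoters (exact 95% interval 66.4 to 84.0%), and among the 741 weakest 27.1% (interval 24.0 to 30.5%). Of the peaks outside promoters, 1 of 24 among the 100 strongest was in coding sequence (4.17%, interval 0.105 to 21.1%), and 201 of 540 among the weakest (37.2%, interval 33.1 to 41.5%). The intervals treat peaks as independent and cover counting error only.

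**Figure D2:**
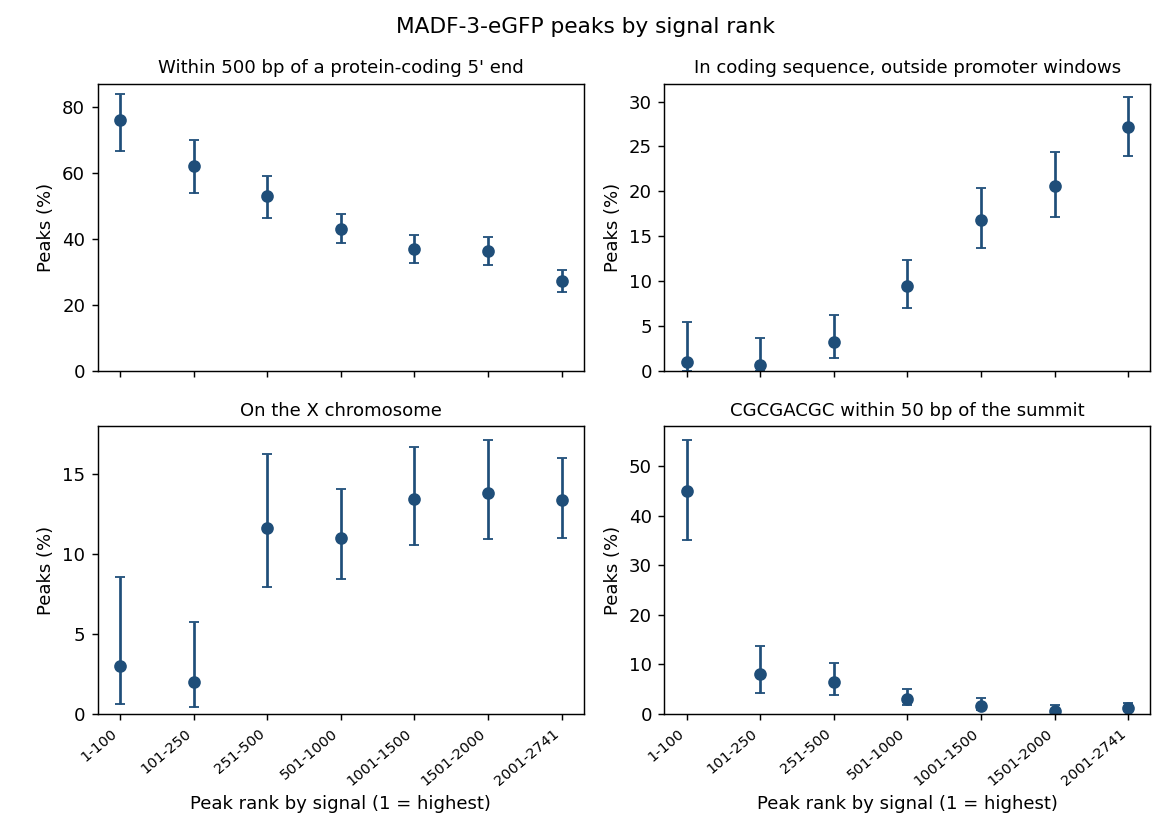
Percent of peaks (y axis) at promoters, in coding sequence outside promoters, on X and with CGCGACGC within 50 bp of the summit, in bins of rank by signal (x axis, 1 is the highest), with exact 95% binomial intervals as bars. Promoter peaks go from 76.0% of the 100 strongest to 27.1% of the 741 weakest, while peaks in coding sequence outside promoters go from 1.00% to 27.1% of all peaks in the bin.

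With a window of 500 bp, ribosomal protein genes had the highest share of members with a promoter peak of the gene lists. Of the 31 gene lists, 12 had promoter peaks more often than other genes, 3 less often and 16 did not pass. With shifts of the peaks along the gene order, a setting added after seeing the data that keeps the number of genes with a peak, the same 12 and 3 lists passed (adjusted permutation p from 0.0062 to 0.041). Shifts of the summits give sets of fewer genes and lost 5 of these calls. Of 81 cytosolic ribosomal protein genes, 50 (61.7%) had a promoter peak, against 6.04% of all other genes (odds ratio 25, 95% interval 16 to 39.4, Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 31 lists, p = 3.0e-38). With a window of 200 bp the odds ratio was 6.55, below oocyte and eggshell genes (11.6), DREAM and synMuv B genes (8.42) and the proteasome (8.36). After rps-19, the strongest was at rpl-3 (WBGene00004414), with 453 ± 41.1 (SD, n = 2) on III from 3867478 to 3867664. Of 37 translation factor genes 9 had a peak (24.3%, odds ratio 4.84, exact adjusted p = 9.4e-04), led by eif-3.C, an initiation factor subunit, with 141 ± 3.36 (SD, n = 2) and eef-1A.1, an elongation factor, with 102 ± 3.65 (SD, n = 2) at a peak nearer to rfc-4. The translation factor call was lost with a window of 200 bp (exact adjusted p = 0.067) and with circular shifts of the summits (permutation p = 0.062 after adjustment, against 0.010 along the gene order), in a range of 1.2e-04 to 0.067 over 11 other settings, and its odds ratio was 7.56 in replicate 1's own list. Mitochondrial ribosomal protein genes did not pass (6 of 70, exact adjusted p = 0.50) except with a window of 1000 bp (exact adjusted p = 0.033, range 0.033 to 1), nor did aminoacyl-tRNA synthetases (5 of 32, exact adjusted p = 0.081), whose 5 genes were ears-2, fars-3, rars-1, gars-1 and vars-1.

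Splicing factor, respiratory chain, proteasome, chaperone and vacuolar ATPase genes also had promoter peaks more often than other genes. Splicing factors had peaks at 11 of 33 genes (odds ratio 7.54, exact adjusted p = 1.55e-05), the strongest at snr-4 and at the peak on II from 11453100 to 11453322 that lies between the divergent SR protein genes rsp-1 and rsp-2, with 516 ± 11.1 (SD, n = 2). The respiratory chain had 14 of 43 (odds ratio 7.30, exact adjusted p = 1.45e-06), led by the cytochrome c oxidase subunits cox-5B, with 237 ± 18.8 (SD, n = 2), and cox-5A, with 188 ± 34.6 (SD, n = 2). The proteasome had 10 of 33 (odds ratio 6.55, exact adjusted p = 8.5e-05), led by rpt-1 and rpn-3, and chaperones 13 of 59 (odds ratio 4.26, exact adjusted p = 2.0e-04), led by the chaperonin subunits cct-7 and cct-8, whose peaks were nearer to T10B5.4 and Y55F3AR.2. Vacuolar ATPase genes had 5 of 20, namely vha-1, vha-18, vha-2, vha-13 and vha-8 (odds ratio 5.00, exact adjusted p = 0.014), of which the peak at vha-18 was nearer to pos-1. The vacuolar ATPase call was lost in 5 of 11 other settings, among them the lists of replicates 2 and 1 alone (exact adjusted p = 0.18 and 0.24, range over all settings 3.5e-04 to 0.61, with odds ratios from 1.62 to 8.28). The chaperone odds ratio was 7.05 and 6.64 in the lists of replicates 2 and 1 alone, and with a window of 200 bp the call was lost (odds ratio 1.65, exact adjusted p = 0.61, range 9.7e-06 to 0.61).

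The same held for the lists of DREAM and synMuv B, oocyte and eggshell, cell cycle, core histone and germline genes. Of 14 DREAM and synMuv B genes, which encode chromatin repressors, 8 had a peak (57.1%, odds ratio 20.1, 95% interval 6.96 to 58.0, exact adjusted p = 3.1e-06). The strongest were at lin-53 (WBGene00003036), a histone-binding protein, with 432 ± 53.6 (SD, n = 2) on I from 9619897 to 9620078, and lin-9 (WBGene00002998), with 142 ± 6.83 (SD, n = 2). Oocyte and eggshell genes had 11 of 22 (odds ratio 15.1, exact adjusted p = 2.1e-07), led by mex-1, an RNA-binding protein of the early embryo, with 349 ± 12.6 (SD, n = 2), and cpg-2, an eggshell proteoglycan, with 82.3 ± 8.44 (SD, n = 2). Cell cycle genes had 9 of 33 (odds ratio 5.65, exact adjusted p = 4.4e-04), led by pcn-1, the replication clamp PCNA, and the cyclin cyb-2.2. Their odds ratio was 11.0 in replicate 2's own list, and with a window of 200 bp the call was lost (exact adjusted p = 0.054, range 7.1e-06 to 0.054). Core histone genes had 12 of 72 (odds ratio 3.01, exact adjusted p = 0.0038), led by his-37 and the peak at his-67 and his-68. Germline and meiosis genes had 7 of 31 (odds ratio 4.38, exact adjusted p = 0.0057), led by glh-2 and pgl-3, which encode proteins of germ granules. The histone call was lost in replicate 1's own list (odds ratio 1.89, exact adjusted p = 0.32, range 2.8e-06 to 0.32). The germline call was lost in the lists of replicates 2 and 1 alone and with 200 bp (exact adjusted p = 0.11, 0.37 and 0.14, range 0.0048 to 0.37), with an odds ratio of 2.22 in replicate 1's list. Both were lost with circular shifts of the summits (adjusted permutation p = 0.19 and 0.15) and passed with shifts along the gene order (adjusted permutation p = 0.019 and 0.040). Against genes with a candidate peak, that is a ranked peak at the promoter, the histone odds ratio was 5.26 (12 of 37 genes). Only these 37 of the 72 histone genes had a candidate peak, compared with 14850 of 19973 protein-coding genes.

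Chemoreceptor, F-box and nuclear hormone receptor genes had promoter peaks less often than other genes. Chemoreceptors had 7 of 1309 (0.535%, odds ratio 0.0753, exact adjusted p = 2.7e-27), F-box genes 4 of 322 (odds ratio 0.186, exact adjusted p = 8.5e-05) and nuclear hormone receptors 4 of 269 (odds ratio 0.223, exact adjusted p = 8.7e-04). The chemoreceptor with the strongest peak was srr-10, with 226 ± 24.9 (SD, n = 2) at a summit -499 bp from its 5' end and nearer to that of clic-1, at -209 bp. It was followed by sri-5. The F-box genes were fbxa-111, fbxb-72, fbxa-56 and fbxa-22, and the nuclear receptors nhr-47, nhr-141, nhr-76 and nhr-23. The nuclear receptor call was lost with a window of 200 bp (exact adjusted p = 0.12) and with circular shifts of the summits (adjusted permutation p = 0.062, against 0.010 along the gene order), in a range of 3.4e-05 to 0.12. In replicate 2's own list 0 of 322 F-box genes had a peak and the nuclear receptor odds ratio was 0.125, and in replicate 1's 1 F-box gene had one (odds ratio 0.0984). The chemoreceptor odds ratio was 0.121 among the 1370 stronger peaks and 0.152 with a window of 1000 bp, while for F-box genes it was 0.0941 in the conservative list and 0.0944 with 200 bp.

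The other lists, among them markers of single tissues, did not pass the test with a window of 500 bp and all other genes as background. Neuron markers had 0 of 28 and bHLH genes 0 of 25 (exact adjusted p = 0.48 for each). Muscle markers had 4 of 27, namely act-2, act-4, unc-60 and unc-15 (exact adjusted p = 0.12), intestinal markers 3 of 15, namely fat-6, cpr-1 and asp-1 (exact adjusted p = 0.098), and vitellogenins 1 of 6, vit-1 (exact adjusted p = 0.40). Neuropeptides had 3 of 140, nlp-59, nlp-18 and ins-37 (exact adjusted p = 0.083), and cuticle collagens 5 of 169, col-85, col-54, col-38, col-131 and bli-6 (exact adjusted p = 0.12). In the direction of fewer peaks, neuropeptides passed in 4 of 11 other settings and collagens in 3 (exact or permutation adjusted p from 0.013 to 0.18 and from 0.026 to 0.37). C-type lectins had 7 of 240 (exact adjusted p = 0.060) and detoxification enzymes 5 of 185, gst-9, gst-1, gst-27, cyp-31A3 and gst-7 (exact adjusted p = 0.081). In the same direction C-type lectins passed in 7 of 11 other settings, each replicate's own list among them, and detoxification enzymes in 3 (exact or permutation adjusted p from 3.1e-04 to 0.19 and from 0.0027 to 0.45). Homeobox genes had 5 of 63, ceh-39, ceh-43, ceh-99, ceh-45 and ceh-38 (exact adjusted p = 0.62), the small RNA pathway 4 of 40, hrde-1, nrde-2, prg-1 and rde-8 (exact adjusted p = 0.40), and autophagy 3 of 24, epg-4, lgg-2 and atg-9 (exact adjusted p = 0.25). With a window of 1000 bp the small RNA pathway and autophagy passed with more peaks (exact adjusted p = 0.013 and 0.028, ranges 0.013 to 1 and 0.028 to 0.70). The p-values over genes describe these peaks only, since genes are not replicates of the experiment. No control list or other factor was used here. The list results therefore cannot separate binding by MADF-3 from signal that active promoters may draw whatever protein is pulled down.

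**Figure D3:**
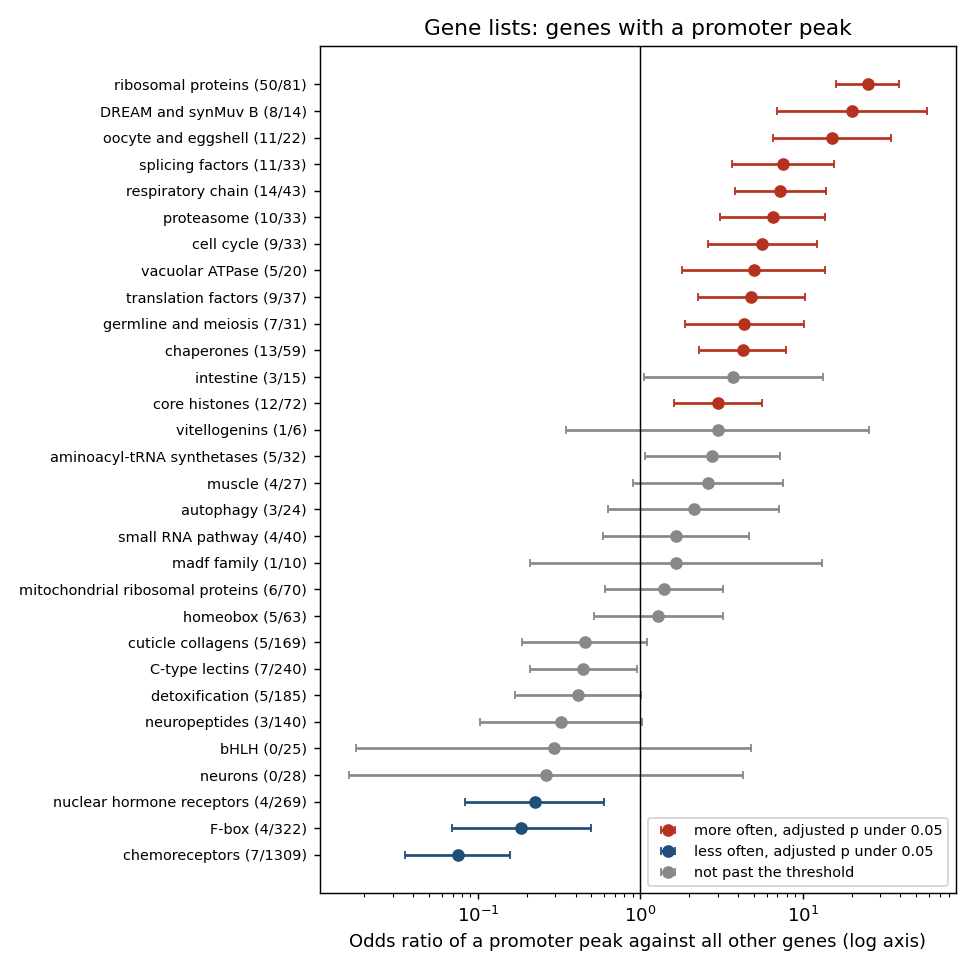
Odds ratio of a promoter peak for each gene list reported here against all other protein-coding genes (x axis, log scale), with 95% intervals as bars and the genes with a peak over the members in brackets. Ribosomal protein genes stand at 25 and chemoreceptors at 0.0753.

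The tagged gene itself had no called peak. No thresholded list held a summit in madf-3 (WBGene00019218, II from 4334748 to 4339038, + strand) or in the 500 bp upstream. The ranked list of 113502 peaks had 4 summits there, the strongest from 4336187 to 4336406 with a signal of 41.2 at rank 16464. Of the 10 madf genes with annotated names, 1 had a promoter peak, madf-11 (WBGene00015468), on III from 5603667 to 5603886 with 38.1 ± 1.39 (SD, n = 2), a list that did not pass (exact adjusted p = 0.51). That peak was in neither replicate's thresholded list, and 0 of 10 had a peak in each of those lists, among the 1370 stronger peaks and with a window of 200 bp, against 2 of 10 with 1000 bp.

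The snoRNA, tRNA and snRNA genes carried peaks more often than shifted peaks gave. Of 346 snoRNA genes, which guide RNA modification, 102 had a summit within 500 bp of the 5' end (29.5% against 2.77% when shifted). For tRNA genes it was 167 of 612 (27.3% against 2.29%) and for the spliceosomal and other snRNA genes 28 of 129 (21.7% against 2.64%). MicroRNA genes had 21 of 261 (8.05% against 2.52%) and genes annotated as ncRNA 460 of 7764 (5.92% against 2.40%). All 5 classes had an adjusted permutation p of 0.0033, the smallest raw p that the shifts can give being 0.0020. In the opposite direction, piRNA genes had 86 of 15363 (0.560% against 2.57%, adjusted permutation p = 0.0033) and pseudogenes 27 of 2128 (1.27% against 2.50%, adjusted permutation p = 0.0057). Observed over shifted counts moved from 10.6 to 17.9 for snoRNA genes in replicate 1's own list and from 0.218 to 0.142 for piRNA genes in replicate 2's. With windows of 200 and 1000 bp it was 25.6 and 6.96 for tRNA, against 11.9 with 500 bp, and 14.2 and 4.68 for snRNA genes, against 8.23. With 200 bp it was 18.4 for snoRNA and 4.19 for ncRNA genes, the latter against 2.46 with 500 bp. The microRNA call was lost in replicate 2's own list and the pseudogene call in replicate 1's (adjusted permutation p = 0.057 and 0.063). Observed over shifted counts were 3.50 there for microRNA genes, against 3.19 in the main list, and 0.520 for pseudogenes, against 0.507. LincRNA (8 of 194), antisense RNA (3 of 100) and rRNA genes (1 of 20) did not pass (adjusted permutation p = 0.34, 0.96 and 0.73).

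**Figure D4:**
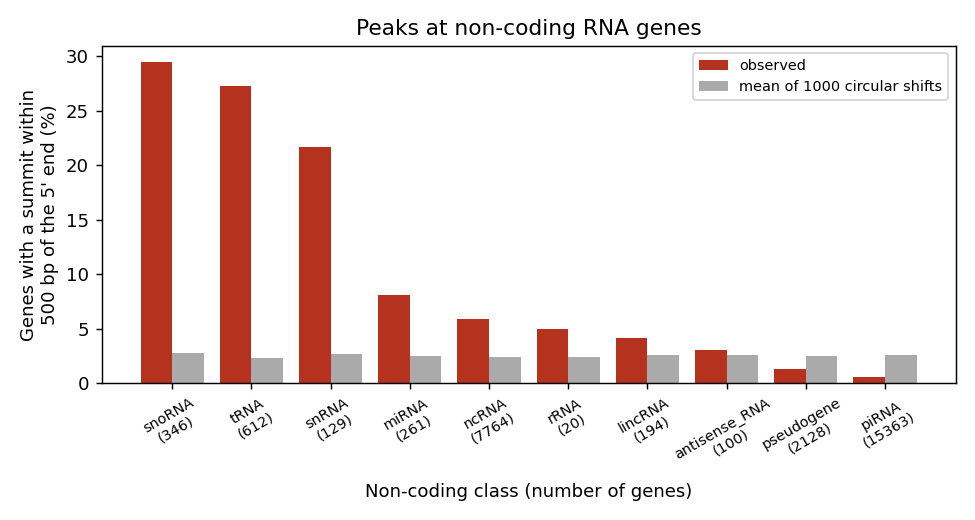
Percent of genes of each non-coding class with a summit within 500 bp of the 5' end (y axis), observed and as the mean of 1000 circular shifts, with no error bars. The snoRNA, tRNA and snRNA classes stand at 29.5%, 27.3% and 21.7%, against 2.77%, 2.29% and 2.64% when shifted.

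The sequence at the summits was rich in G and C. Mean GC was 46.9% within 50 bp of the summit and 36.0% in flanks 200 to 300 bp away, a difference of 10.9 percentage points (SD 9.94 over 2741 peaks, sign-flip permutation p = 1e-05, the smallest it can give). Of 2297 8-mers tested on chromosomes I, III and V, 154 were more frequent at summits than in flanks, and 97 of them also passed on the held-out chromosomes II, IV and X. Fewer enriched 8-mers passed among the 1370 stronger peaks (37) and in the lists of replicates 2 and 1 alone (15 and 23), which hold fewer peaks. In the other direction 541 were less frequent at summits, and 315 of them passed on the held-out chromosomes, led on I, III and V by AAAAAAAA, at 38 summits and 145 flanks of the held-out set (exact adjusted p = 2.9e-14). That count was 179 with flanks 400 to 500 bp away on the same peaks, and from fewer peaks 117 among the stronger ones, 39 and 44 in the lists of replicates 2 and 1 alone and 44 at promoters. Among 8-mers more frequent at summits, the lowest p on I, III and V belonged to CGCGACGC, found at 55 of 1512 summits and 3 flanks on I, III and V and at 52 of 1229 summits and 4 flanks on II, IV and X (exact McNemar test, exact adjusted p = 1.1e-09 on the held-out set). The next was AGACGCAG, at 40 summits and 5 flanks of the held-out set (exact adjusted p = 1.7e-06), followed by GCGAGACC, at 37 and 2 (exact adjusted p = 9.4e-08). Of the 11 sequences listed before the data were examined, the E-box CACGTG was at 90 summits and 40 flanks (exact adjusted p = 4.3e-05) and the GAGA repeat at 52 and 24 (exact adjusted p = 0.0048), a difference of 1.02 percentage points that was 1.62 in replicate 2's own list and 1.61 among the 1370 stronger peaks. The GATA sequence TGATAA was at 122 summits and 231 flanks (exact adjusted p = 1.45e-08), a difference of -3.98 percentage points that was -6.95 in replicate 2's own list, and the TATA box at 116 and 318 (exact adjusted p = 3.9e-23). The E2F, GC box, heat shock element, SKN-1, FOXO, AP-1 and CCAAT sequences did not pass (exact adjusted p from 0.13 to 1). E2F, at 32 summits and 18 flanks, passed in the conservative list and with flanks 400 to 500 bp away (exact adjusted p = 0.0064 and 0.012, range 0.0064 to 0.70), and the heat shock element with those flanks (exact adjusted p = 0.030, range 0.030 to 0.58). The E-box difference was 1.82 percentage points. It did not pass among the 1370 stronger peaks (0.657 points, exact adjusted p = 0.51) or in replicate 2's own list (1.39 points, exact adjusted p = 0.098), in a range of 3.1e-04 to 0.51. The 8-mer and fixed-sequence tests did not correct for the higher GC at summits. They therefore cannot separate a difference in a given sequence from the difference in base composition. Only CGCGACGC was set against 8-mers of the same composition, in the closing part.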

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

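The tests of X coverage, identical RNA gene copies, copies by class and base composition below were chosen after the result was seen. Also chosen after seeing the data were the 250 strongest peaks, the RNA genes far from protein-coding 5' ends and the test of CGCGACGC within promoter peaks. No biological explanation was tested for any of the 3 patterns, since the samples form 1 group.

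Ranked peaks with high signal lay outside the main list. Of the 2956 ranked peaks with a score at or above the lowest of the thresholded list, 215 (7.27%) were missing from that list. They include 4 of the 10 strongest and the strongest of all, on X from 15810979 to 15811178, with a signal of 3508 against 3403 for the strongest peak kept. Its signal was 1828 in replicate 1's ranked list and 1954 in replicate 2's. Of the 215, 185 were intergenic, 8 were at promoters and 37 were on X. Per the deposited descriptions the thresholded list was made with 1 more input file than the ranked list, and what that file holds is not given in the sources used here. Whether these peaks were taken out as regions on an exclusion list was not tested, so their signal is not read as binding.

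The first pattern is the low number of peaks on X. Poorer read coverage or mapping on X stays open. Of the ranked peaks that missed the threshold, 19.4% were on X (exact 95% interval 19.2 to 19.6%), above X's 17.7% of the length. This share cannot decide the question, because weaker signal on X would also move its peaks below the threshold, and depth is unknown. The lower number of protein-coding genes on X is argued against as the cause at promoters. There, 62 of 2731 X genes and 1189 of 17242 autosomal genes had a peak (odds ratio 0.314, 95% interval 0.242 to 0.406). Over all peaks, most of them outside promoters, the ratio moves from 0.671 to 0.867 when set against X's share of genes. That move cannot tell how much gene number covers, because it sets peaks outside promoters against a share of genes. Other differences between X and autosomes stay open, such as the low share of germline-expressed genes on X, which was not tested.

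The second pattern is the frequency of peaks at tRNA, snoRNA and snRNA genes. Neighbouring protein-coding promoters are argued against as the whole cause, since 23.8% of the 718 such genes over 1000 bp from a protein-coding 5' end had a peak, above the 4.87% of the highest shift. Reads shared between identical copies are argued against as the whole cause too. Of the 574 genes whose sequence occurs once, 26.8% had a peak, above the 5.05% of the highest shift. So had 21.7% of such tRNA, 29.5% of snoRNA and 24.7% of snRNA genes, above 6.99%, 7.23% and 12.9%. A part played by identical copies stays open. Among genes with an identical copy, 29.0% of 469 tRNA genes and 15.9% of 44 snRNA genes had a peak. Reads shared between near-identical copies cannot be told apart from binding here, because the odds ratio of a peak for genes without against genes with an identical copy had a 95% interval holding 1 over all (0.949, 0.726 to 1.24), for tRNA (0.678, 0.434 to 1.06) and for snRNA genes (1.73, 0.673 to 4.47), while all 346 snoRNA genes occur once. Active tRNA genes may also draw chromatin signal whatever protein is pulled down, and with no control list or other factor used here that stays open.

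The third pattern is the 8-mer CGCGACGC at the strongest peaks, where it was at 57 of 250 summits (22.8%) and at 50 of the other 2491 (2.01%). On II, IV and X, which were not used to find it, it was at 25 of 103 and 27 of 1126 (odds ratio 13.0, 95% interval 7.23 to 23.5). That strong peaks lie at promoters is argued against as the cause, since within promoter peaks the odds ratio was 21 (95% interval 11.5 to 38.2). High GC content is argued against by the 279 other 8-mers of the same composition, whose 99th percentile on those chromosomes was 5.22 peaks against 25, with the overlapping CCGCGACG next at 11. The match was by base counts only, so the order of bases, such as the number of CG pairs, was not matched. A candidate explanation is that CGCGACGC is part of a sequence bound by MADF-3 or by a partner, which these peaks alone do not test.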

How the results depend on the processing

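The shifts along the gene order, the 250 strongest peaks, the promoter-only 8-mers, the summits outside coding sequence, all tests of regions other than promoters and the RNA genes far from protein-coding 5' ends were chosen after seeing the data. The X, centre, promoter, GC and overlap results kept their direction and stayed past the threshold in every setting run for them, and madf-3 had 0 peaks in each. Each replicate alone, whose list is shorter by construction, gave 570 to 604 genes with a promoter peak, 4 to 5 lists with fewer peaks and 15 to 23 enriched 8-mers, against 1251, 3 and 97. The 1370 stronger peaks gave 799 genes, 6 such lists and 37 8-mers, also from fewer peaks. A window of 200 bp gave 629 genes and 7 lists with more peaks against 12. Lists with fewer peaks numbered 5 in the conservative list, 5 with a window of 1000 bp and 7 against named genes alone, and the cause was not tested. Promoter peaks alone gave 22 8-mers, from fewer peaks. The rank correlation of the replicates' signals was 0.359 over all ranked peaks, which adds the weak ones. With circular shifts of the summits, neurons and bHLH genes passed with 0 members holding a promoter peak (adjusted permutation p = 0.0077 each). The call comes from the statistic, because a shifted set holds fewer genes and so cannot reach as low an odds ratio. Along the gene order neither passed (adjusted permutation p = 0.41 and 0.51).

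Among summits outside promoters, ratios to the shifts turned from 0.868 to 1.17 for intergenic space and from 0.831 to 1.12 for coding sequence, because the share of all summits falls as the promoter share rises, and 5' UTRs then passed. Other directions changed only for items that passed in neither setting. Odds ratios fell below 1 for mitochondrial ribosomal proteins (0.926 in the conservative list, 0.347 in the stronger peaks, 0.464 to 0.492 in single replicates), homeobox genes (0.386 in the stronger peaks, 0.251 to 0.267 in single replicates), aminoacyl-tRNA synthetases (0.522 without replicate 1, 1.03 without replicate 2), and with 200 bp the small RNA pathway (0.788) and muscle (0.558). Ratios to the shifts fell below 1 for antisense RNA (0.755 in the stronger peaks, 0 without replicate 2 and with 200 bp, 1.17 without replicate 1, 0.636 far from 5' ends), rRNA (0 in the stronger peaks and in each replicate) and lincRNA (0 without replicate 1, 1.12 without replicate 2). The difference in percentage points turned for AP-1 (0.228 in the conservative list, 0.0730 in the stronger peaks, 0.109 with far flanks), FOXO (-0.116 without replicate 1) and CCAAT (-0.695 and -1.14 in single replicates, -0.219 with far flanks). The cause was not tested. Of the other settings, 17 list calls were lost and 22 gained, 2 RNA class calls were lost, and 2 sequence calls were lost and 3 gained. Unknown depth limits all counts of peaks.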

Other observations

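All gene families in this part were chosen after seeing the data, by taking every name prefix with at least 10 genes that the 31 lists did not mostly cover, and so were the comparisons by rank. Of 125 such families, 4 had promoter peaks more often than other genes and 0 less often at an adjusted p under 0.05. The families are given for the main setting only, and genes that share a peak were counted separately. Nucleoporins, the proteins of the nuclear pore, had 8 of 26 (npp genes, odds ratio 6.69, Fisher's exact test, exact adjusted p = 0.016). Among them was npp-7, whose peak was nearer to unc-40. Subunits of Mediator, which links transcription factors to RNA polymerase II, had 6 of 20 (mdt genes, odds ratio 6.44, exact adjusted p = 0.034). RNA-binding motif genes had 5 of 13, namely rbm-39, rbm-12, rbm-3.1, rbm-3.2 and rbm-7 (odds ratio 9.39, exact adjusted p = 0.034). The lin genes had 10 of 47 (odds ratio 4.07, exact adjusted p = 0.034), and 7 of those 10 are also in the DREAM and synMuv B list.

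Peaks within 100 bp of tRNA genes were absent from the 250 strongest peaks, and made up 42 of the 500 peaks ranked 501 to 1000 (8.40%, exact 95% interval 6.12 to 11.2%) and 26 of the 741 weakest (3.51%, interval 2.30 to 5.10%). The 8-mer AGACGCAG was at 11 of the 100 strongest summits (11.0%, interval 5.62 to 18.8%) and at 22 of the 741 weakest (2.97%, interval 1.87 to 4.46%).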
